A study of Oryza sativa with 4 samples.

How the data were processed

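ATAC-seq was run on leaf blades of rice seedlings, with 2 libraries of the Oshmgb1 mutant and 2 of WT, all under the same HP treatment of 28 days per the labels. Per the labels' protocols, nuclei were incubated with Tn5 transposase and libraries were made with a transposase library kit. Per the submitters' processing notes, the tools used were bcl2fastq 2.19, fastp 0.23.0, Bowtie2 2.4.4, MACS2 2.1.2 and ChIPseeker 1.16.1. The notes give no order or settings. The genome build, the Tn5 shift of reads, the removal of duplicates and of organelle reads, and the test behind the authors' own p-values are not given in the sources used here. If the shift was left out, cut sites would move by a few bases, which is small beside peaks of 201 to 4473 bp (median 560 bp). Duplicates left in would raise counts without adding molecules.

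The deposited table has 1 row per merged peak, with read counts per library, RPKM per library, the authors' group means, a log2 fold change, a p-value and an FDR, an annotation class, a gene and its description. The read counts deposited by the authors are whole numbers per peak and library, not normalised, and they were the values tested here. The RPKM deposited by the authors were used only to work out the library total that each column was divided by, as the median over peaks with more than 300 reads. The log2 fold change deposited by the authors is the log2 ratio of their group means of RPKM. The p-value and FDR deposited by the authors were used as an alternative set of calls. Per the file headers no column belongs to another sample, and 0 such columns were found. Peak numbers run to 57405, of which 46114 (80.3%) are listed. The authors' FDR values fit ranks among all numbered peaks: 11 of the 12 smallest p-values gave a whole rank within 0.2. The smallest listed p-value had an implied rank of 4, and the last of the 47 listed at an FDR under 0.05 had 66. The listed rows thus appear not to hold all of the authors' calls. The unlisted peaks were not analysed here, and library totals were therefore also taken from the RPKM as an alternative. The classes have no distal group.

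Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, the default expression filter, which removed no peak, and the quasi-likelihood test of Oshmgb1 against WT with no covariates, at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the fold change and the F statistic, and intervals are 95%. Gene lists were tested with camera (preset correlation 0.01, and an estimated one) and fry from limma 3.58.1 on promoter peaks as annotated by the authors, for lists of at least 3 peaks, and with Fisher's exact test per direction against all other promoter peaks. Annotation classes and chromosomes were tested with Fisher's exact test. DESeq2 1.42.0 was the alternative test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

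The groups, tests, alternatives, 30 gene lists and the rule for named genes were set before the data were examined. The rule names OsHMGB1 always, up to 12 members of the phosphate list past the threshold, and the 10 largest positive and 10 largest negative promoter peaks past the threshold. The last had to have at least median accessibility, no overlap between genotypes, a gene with a name or description that is not a transposon, and 1 peak per gene. Only 7 and 8 genes passed these conditions. Up to 2 members past the threshold were added from every other list, giving 17 called peaks. Gene identifiers, symbols and descriptions are those of the deposited table, and some symbols are borrowed from other species. LOC_Os06g51220 was taken as OsHMGB1 from background knowledge. Phosphate genes were listed by identifier, also from background knowledge, and other lists by words in the descriptions.

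Depth ranged from 7228483 to 10400677 reads in listed peaks, with medians of 105, 121, 155 and 127 reads per peak in WT replicates 1 and 2 and Oshmgb1 replicates 1 and 2. The WT replicates differed by more than counting noise (chi-square per degree of freedom 2.50), as did the Oshmgb1 replicates (2.25), so no library was counted as a duplicate. Nothing in the labels says that the libraries came from separate plants or cultures, so p-values measure the spread between these libraries, which may be technical. With 2 libraries against 2, leaving 1 out puts a lone library in an arm, which the fit assumes to vary like the others. On simulated counts with the same means, depths and spread, the test recovered 20% of 50 peaks changed 1.5-fold, 88% changed 2-fold and 100% changed 3-fold and 4-fold. It made 7 false calls among 46114 peaks. A simulated list of 40 peaks shifted by 0.3 was found, and 0 unchanged lists were called. The simulated peaks were drawn independently of one another. This therefore does not show the power of the list tests where peaks vary together.

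Alternatives were DESeq2's test and its size factors, library totals alone, library totals behind the RPKM, no filter, at least 20 counts in 2 libraries, an adjusted p under 0.01, an absolute log2 fold change of at least 1, the authors' calls, unplaced sequences left out, the replicate number as a block, and each replicate left out. For lists, all peaks of a gene and promoters within 1000 bp were tried. For classes, gene body classes were pooled. Chosen after the data were seen were an intensity-dependent offset (loess span 0.3), testing only peaks of at least median abundance, thinning all libraries to the smallest depth, and matching list words regardless of letter case. The RefSeq gene table used here has no identifiers shared with the deposited table and gave no names.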

Results

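Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in leaf blades of rice (Oryza sativa) seedlings kept for 28 days under the regime that the labels call HP. The 4 libraries came from 2 genotypes, with 2 libraries of the Oshmgb1 mutant and 2 of the wild type (WT). OsHMGB1 is a high mobility group box protein, a small non-histone protein that binds and bends DNA in chromatin. The series title ties it to phosphate homeostasis and plant growth. Reads in the 46114 listed peaks numbered 7228483 and 8183354 in WT replicates 1 and 2, and 10400677 and 8516630 in Oshmgb1 replicates 1 and 2. These were 27.2% ± 0.354 (SD, n = 2) of the library totals behind the deposited RPKM in WT and 26.0% ± 0.169 (SD, n = 2) in Oshmgb1. Across peaks, log2 values correlated at 0.950 between the WT libraries and at 0.960 between the Oshmgb1 libraries, against 0.931 to 0.946 between genotypes, where peaks are not independent replicates. Values below are read counts scaled to library size (CPM) as mean ± SD with n = 2 per genotype, and log2 fold changes are Oshmgb1 over WT with their standard errors (SE).

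The mutated gene itself, OsHMGB1 (LOC_Os06g51220, listed with the symbol HMGB2) had promoter and exon peaks with reads in all 4 libraries. Its promoter peak on chromosome 6, 30991770 to 30993556, measured 130 ± 8.22 CPM in WT and 114 ± 1.62 CPM in Oshmgb1. The log2 fold change was -0.19 ± 0.10 (SE), with an edgeR adjusted p of 0.396, so it was not called. The second peak of the gene, in an exon at 30994103 to 30994794, measured 31.3 ± 0.555 and 29.3 ± 0.844 CPM, with a log2 fold change of -0.09 and an adjusted p of 0.843. Accessibility at these peaks does not test the genotype label, since the kind of mutation is not given in the sources used here.

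The comparison of Oshmgb1 with WT asked where chromatin is more or less open in leaves of the mutant. Of 46114 peaks, 148 were more accessible in Oshmgb1 and 38 less accessible, at 177 genes. Among called promoter peaks of at least median accessibility at genes with a name, the largest gain was at LOC_Os12g07180, described as a homologue of disheveled-associated activator of morphogenesis 1, which rose from 13.0 ± 3.72 to 28.0 ± 1.95 CPM. The largest loss among them was at MADS55, a MADS-box transcription factor of the group that represses flowering, which fell from 29.9 ± 0.683 to 17.4 ± 1.19 CPM. SBE1 (LOC_Os02g32660), described as a starch-branching enzyme, fell from 25.3 ± 0.712 to 15.3 ± 0.298 CPM. The median log2 fold change was 1.06 over the higher peaks, where the largest change was 4.28-fold, and -0.90 over the lower peaks, which reached -1.35. At least 2-fold change was seen in 101 of the called peaks.

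The same rule, which keeps 1 peak per gene, named 7 of the 53 promoter peaks that rose, the other 6 at LOC_Os09g17680 (a probable NADH kinase, log2 fold change 0.96 ± 0.20 SE), RhGT1 (LOC_Os05g45080, an anthocyanidin glucosyltransferase by its description, 0.95 ± 0.19), LCV3 (LOC_Os12g29750, 0.82 ± 0.17), ALY3 (LOC_Os01g09760, 0.80 ± 0.20), MAIL3 (LOC_Os07g13390, 0.78 ± 0.18) and HST1 (LOC_Os11g31770, 0.63 ± 0.16). The adjusted p of these 6 ran from 0.00126 for RhGT1 to 0.0493 for HST1. A second promoter peak of LOC_Os09g17680, below median accessibility (chromosome 9, 10813055 to 10813602), was named after its values were seen. It rose from 7.39 ± 1.13 to 18.4 ± 0.585 CPM (adjusted p 4.79e-05) and was called by edgeR, by DESeq2, in the authors' deposited table and with each library left out. The peak at LOC_Os12g07180 (chromosome 12, 3528125 to 3528724, 414 bp upstream of the gene start) had a log2 fold change of 1.09 ± 0.18 and an adjusted p of 4.79e-05. Promoter peaks that fell included LOC_Os10g22330, an AP-4 adaptor complex sigma subunit (-0.70 ± 0.16), LOC_Os01g29220, a piezo-type mechanosensitive channel homologue (-0.63 ± 0.14), and LOC_Os06g15820, an NHL domain protein (-0.52 ± 0.13). The MADS55 peak (LOC_Os06g11330, chromosome 6, 5963120 to 5963875, 313 bp upstream) had a log2 fold change of -0.79 ± 0.17 and an adjusted p of 0.00412, and the SBE1 peak (chromosome 2, 19367418 to 19368205, 684 bp upstream) had -0.73 ± 0.18 and an adjusted p of 0.0273.

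**Figure D1:**
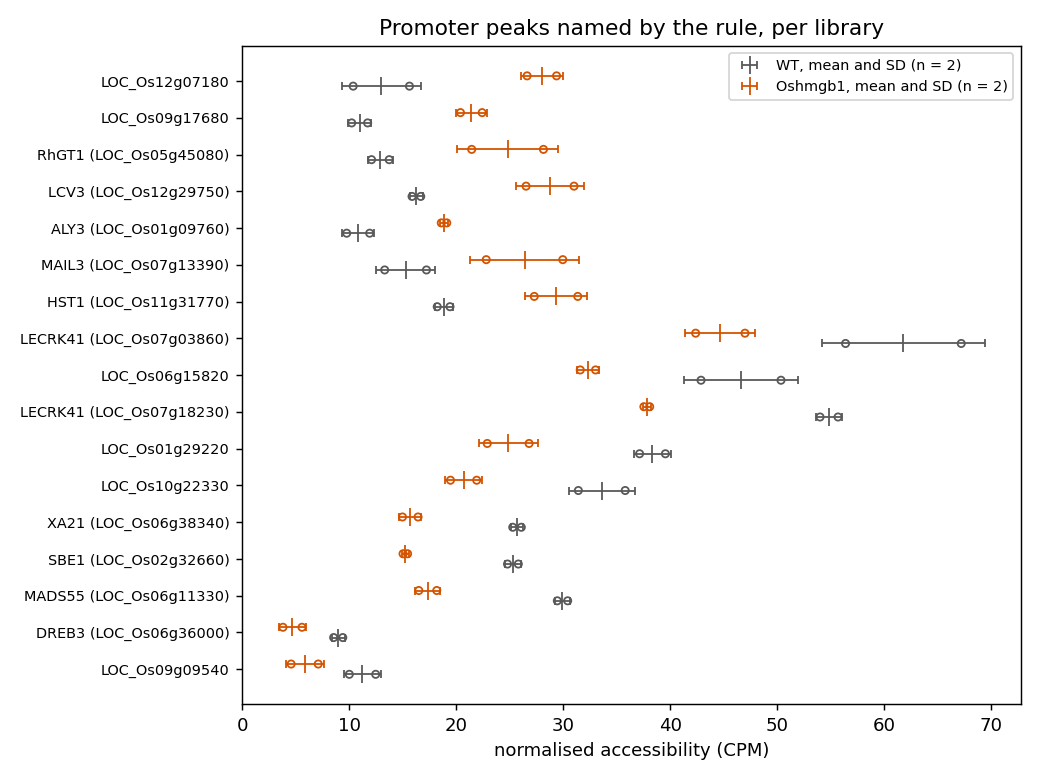
Normalised accessibility (CPM) of the 17 called promoter peaks named by the rule, with each library as a circle and the mean and SD (n = 2) of WT in grey and Oshmgb1 in orange. LECRK41 at LOC_Os07g03860 has the highest WT mean, 61.8 CPM.

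The smallest p-values fell on peaks outside the promoter class or at genes without a description, which were picked for naming after their values were seen. A peak just downstream of ARD4 (LOC_Os10g28360, an acireductone dioxygenase of the methionine salvage cycle) rose from 18.5 ± 2.63 to 54.3 ± 1.57 CPM (chromosome 10, 14756029 to 14756942, adjusted p 1.64e-14). The 5′ UTR peak of LOC_Os10g22630, listed as an expressed protein, rose from 7.89 ± 2.34 to 33.5 ± 0.996 CPM. Peaks downstream of GLTP2 (LOC_Os08g01710) and of NET4B (LOC_Os05g07680, described as a NETWORKED protein of the actin-binding family) had log2 fold changes of 1.62 ± 0.16 and 1.52 ± 0.16. An exon peak of YUC10 (LOC_Os02g17230) and an intron peak of YUC5 (LOC_Os01g25470), whose symbols are those of flavin monooxygenases of auxin synthesis, had 1.24 ± 0.21 and 0.97 ± 0.19. In the other direction, an exon peak of LOC_Os02g10570, an Ulp1 protease-like gene, fell from 33.8 ± 1.36 to 15.2 ± 0.531 CPM. All of these except YUC5 were among 38 peaks, 36 higher and 2 lower, that were called in the same direction by edgeR, by DESeq2, in the authors' deposited table and with each library left out in turn.

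These counts come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Both libraries of one genotype lay above both of the other in 43.2% of all peaks, which chance alone gives in 33.3%. At an unadjusted p under 0.05 there were 5606 peaks (12.2%), and in 95.2% of peaks the 95% interval excluded a 2-fold difference. The higher share of called peaks was 79.6%, and 60.2% (133 higher, 88 lower) when scaled by the library totals behind the RPKM. DESeq2 called 45 peaks and the authors' deposited table lists 47 at an FDR under 0.05, while leaving out WT replicate 2, Oshmgb1 replicate 1 or Oshmgb1 replicate 2 gave 530, 103 or 75. Of the 17 named promoter peaks, DESeq2 called only LOC_Os12g07180 and the authors' deposited table only LOC_Os12g07180 and MADS55, and 3 and 5 passed without Oshmgb1 replicates 1 and 2. The replicate number as a block ended 3 of these calls with nearly the same log2 fold changes, HST1 (0.64, adjusted p 0.0534), LECRK41 at LOC_Os07g03860 (-0.46, 0.0542) and DREB3 (-0.94, 0.0541).

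**Figure D2:**
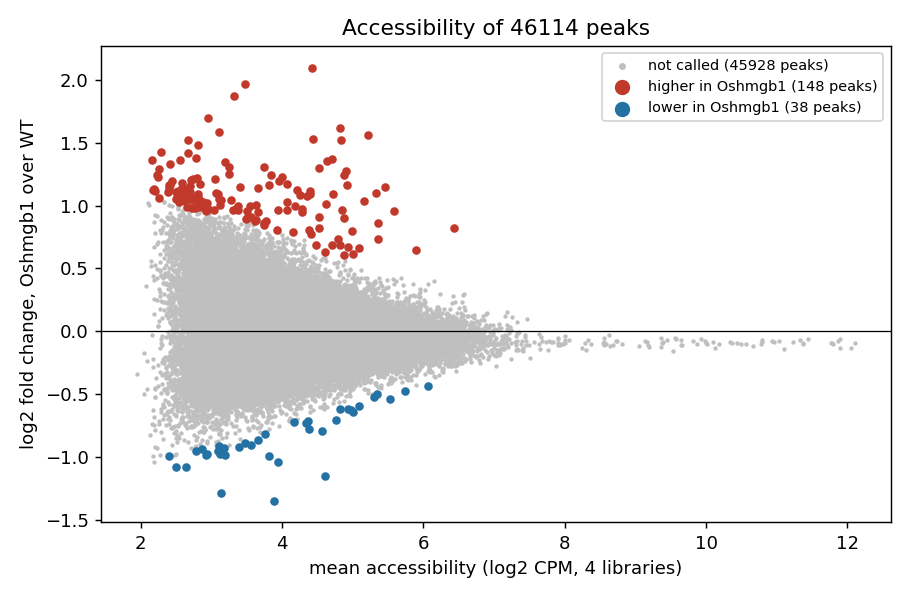
Each point is 1 of 46114 peaks, with mean accessibility over the 4 libraries (log2 CPM) on the horizontal axis and the log2 fold change of Oshmgb1 over WT on the vertical axis. The 148 higher peaks (red) outnumber the 38 lower peaks (blue), and many of them lie at the weak end of the axis.

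Genes of phosphate signalling and transport were examined because the series title names phosphate homeostasis. Of the 40 genes of this list, 32 had a peak of any class, and 0 of their 62 peaks were called. Only 16 of the genes had a promoter peak, so the values for the list do not cover the others. None of the 23 promoter peaks at these 16 genes was called. Among these promoter peaks, the lowest unadjusted p-values were at OsPTF1 (LOC_Os06g09370, a transcription factor of low-phosphate tolerance, log2 fold change -0.35 ± 0.13 SE, adjusted p 0.224), OsSPX-MFS3 (LOC_Os06g03860, a vacuolar phosphate transporter, -0.31 ± 0.13, adjusted p 0.297) and OsSPX-MFS1 (LOC_Os04g48390, of the same family, -0.39 ± 0.17, adjusted p 0.311). The promoter peak of OsPHR2 (LOC_Os07g25710), the central regulator of phosphate starvation responses, had 0.03 ± 0.11, and the 5′ UTR peak of the transporter OsPT8 (LOC_Os10g30790) had -0.35 ± 0.19 with an adjusted p of 0.471. A 5′ UTR peak of the acid phosphatase OsPAP10a (LOC_Os01g56880) had 0.71 ± 0.20, with an unadjusted edgeR p of 5.31e-04 and an adjusted p of 0.0782. By its class it is not among the 23 promoter peaks, so the values for the list that follow leave it out. Adjusted over the list alone, 0 of the 23 promoter peaks passed. At an unadjusted p under 0.05, edgeR gave 3 of them, DESeq2 gave 1 and 3 had it in the authors' deposited table, and neither of the latter called any after adjustment. The median of the list was 0.03, its mean -0.06 and the direction of camera, a gene set test, down (adjusted p 0.626, and adjusted p = 0.976 with an estimated correlation). A 2-fold difference was excluded by the 95% interval in 23 of 23 peaks. A wider list of phosphate transporter, SPX domain and acid phosphatase descriptions had 22 promoter peaks, 0 called by edgeR, DESeq2 or the authors' deposited table, and 3 at an unadjusted p under 0.05 in edgeR.

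Receptor kinases lost accessibility at 4 of their 263 promoter peaks and gained it at 0. The 4 were LECRK41 at LOC_Os07g18230 (chromosome 7, 10807873 to 10809138, -0.54 ± 0.12 SE), LECRK41 at LOC_Os07g03860 (chromosome 7, 1612134 to 1613198, -0.47 ± 0.12), a gene with the symbol XA21 at LOC_Os06g38340 (chromosome 6, 22715505 to 22716250, -0.71 ± 0.18), and RLP51 at LOC_Os01g54630 (-0.91 ± 0.24), which falls outside the rule and was named after its values were seen. LECRK41 is described as a lectin-domain receptor kinase and the XA21 entry as an LRR receptor kinase, both families of cell-surface receptors. The lower calls made up 1.52% of the list against 0.101% of the other promoter peaks (odds ratio 15.3, two-sided Fisher's exact test, p 2.69e-04, adjusted p 0.0140 over 52 tests). Adjusted over the list alone, 7 peaks were lower and 1 higher. The enrichment did not pass over all peaks of the genes (odds ratio 6.54, adjusted p 0.252) or within 1000 bp of the gene start (9.80, 0.650). With library totals alone the odds ratio was again 15.3, but the adjusted p was 0.0869. Nor did it pass with the intensity-dependent offset (odds ratio 8.70, 2 lower peaks), with the replicate number as a block (9.37, 2 lower peaks) or with any library left out. Without WT replicate 2 the odds ratio was 0.864.

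Of the other 25 lists with at least 3 promoter peaks, the ethylene response factors and the transposon-related genes each had 1 called peak. DREB3 (LOC_Os06g36000) fell from 8.98 ± 0.602 to 4.71 ± 1.26 CPM (log2 fold change -0.95 ± 0.25, adjusted p 0.0493), and LOC_Os09g09540, a Mutator-like transposase, fell from 11.3 ± 1.74 to 5.85 ± 1.79 CPM (-0.96 ± 0.24, adjusted p 0.0366). No promoter peak was called among the 28 of photosynthesis, the 36 of histones, the 6 of high mobility group proteins, the 46 of chromatin regulators, the 58 of WRKY, 28 of MYB, 37 of NAC and 36 of bHLH factors, or the 117 of defence genes. The same held for the hormone lists, with 83 peaks of auxin, 12 of gibberellin, 28 of cytokinin, 15 of abscisic acid and dehydration and 21 of jasmonate genes. It also held for 37 peaks of cell wall growth, 164 of ribosomal proteins, 50 of heat shock, 14 of iron, 39 of nitrogen uptake and 15 of cell cycle genes, and for 5 of mesophyll markers. Together with both phosphate lists these 23 lists had 920 promoter peak entries, of which 107 had an unadjusted edgeR p under 0.05 (38 in DESeq2 and 52 in the authors' deposited table). Neither DESeq2 nor the authors' deposited table called a peak of any list.

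Adjusted over the list alone, some further peaks passed that failed over all peaks, and these were named after their values were seen. They were higher at RBCS (LOC_Os12g17600, the Rubisco small subunit, log2 fold change 0.50 ± 0.18), WRKY62 (0.82 ± 0.24), ERF113 (0.89 ± 0.26) and BHLH83 (0.88 ± 0.26). They were also higher at 3 defence genes, PRMS at LOC_Os02g54560 and LOC_Os10g11500 and a disease resistance gene at LOC_Os11g42770. The RBCS peak lay 1718 bp upstream, while the stronger 5′ UTR peak of that gene had -0.07 ± 0.11 and its 3′ UTR peak -0.04. Peaks of this kind were lower at the defence gene RPP13 (LOC_Os08g07774, -0.41 ± 0.12) and at the transposon-related LOC_Os11g44270 (-0.56 ± 0.15). The lists of meristem, vascular, epidermis and root markers had 0, 1, 1 and 1 promoter peaks, 0 of them called and 0 at an unadjusted p under 0.05, and were too small to test. Camera and the one-directional fry test passed 0 of 26 lists, with 0 at an unadjusted p under 0.05 in either, the lowest adjusted p being 0.626 and 0.725, and 0.976 for camera with an estimated correlation. With the replicate number as a block, fry passed 1 list, the MYB factors (adjusted p 0.0159). Fry's mixed test, which asks whether members change in either direction and does not compare them with other genes, gave an adjusted p of 0.00466 for receptor kinases, 0.0157 for photosynthesis, 0.0182 for cell cycle and for transposon-related genes, 0.0426 for auxin and 0.0478 for nitrogen uptake. Median and mean differed in sign for 6 lists, those of phosphate signalling, mesophyll markers, defence, WRKY, abscisic acid and transposon-related genes.

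Peaks downstream of genes were more often gained than peaks elsewhere. In this class, which holds the ARD4, GLTP2 and NET4B peaks, 32 of 5390 peaks (0.594%) were higher in Oshmgb1 against 0.285% of other peaks (odds ratio 2.09, two-sided Fisher's exact test, adjusted p 0.00582). Promoters held 53 of the higher and 20 of the lower peaks, and the lower peaks were 0.124% of promoter peaks against 0.0601% elsewhere (odds ratio 2.06, adjusted p 0.0815, not past the threshold). In 3′ UTRs 4 and in 5′ UTRs 3 peaks were higher, a smaller share than elsewhere (adjusted p 0.0762 for each). This passed for both with library totals alone (0.0228 for each) and without WT replicate 2 (0.0283 and 4.28e-04), and for 3′ UTRs with the replicate block (0.0427). Exons and introns had 29 and 27 higher peaks, with an adjusted p of 1. Peaks are not independent replicates, so these tests describe this set of calls. The downstream excess did not pass among peaks with at least 2-fold change (19 peaks, adjusted p 0.0971) or without Oshmgb1 replicate 1 (15 peaks, adjusted p 0.543).

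Higher peaks were unevenly spread over the chromosomes. Chromosomes 10, 12 and 5 had 21 of 2701, 21 of 2801 and 23 of 3777 peaks higher in Oshmgb1 (odds ratios 2.67, 2.57 and 2.07, two-sided Fisher's exact test, adjusted p 0.00373, 0.00415 and 0.0222). Chromosomes 1, 3 and 6 had fewer than the rest, with 9, 7 and 3 higher peaks (adjusted p 0.0290, 0.0290 and 0.0199). Chromosome 6, which carries MADS55, DREB3 and the XA21 entry, had 8 of the lower peaks (odds ratio 2.98, adjusted p 0.0376). Peaks are not independent replicates, and some of the higher peaks on chromosomes 10 and 12 lay side by side in groups. These tests count each such peak separately and therefore describe this set of calls. The excess on chromosome 10 did not pass without WT replicate 2 (odds ratio 1.375) or without Oshmgb1 replicate 1 (odds ratio 2.51). That on chromosome 12 did not pass among peaks with at least 2-fold change (odds ratio 2.03, adjusted p 0.191). Nor did it pass without Oshmgb1 replicate 1 (odds ratio 2.41) or 2 (odds ratio 2.63). The calls on chromosomes 1, 3, 5 and 6 were each lost with the intensity-dependent offset. There the odds ratios for higher peaks on chromosomes 1, 3 and 6 were 0.4334, 0.3317 and 0.2367, against 0.4206, 0.3785 and 0.2299 by default. That for higher peaks on chromosome 5 was 1.76 against 2.07, and that for lower peaks on chromosome 6 was 1.67 against 2.98. These calls were also each lost in at least 3 of the 4 fits that leave out a library. The odds ratio for lower peaks on chromosome 6 was 0.929 without Oshmgb1 replicate 2. The share of reads on each chromosome differed little between libraries. Chromosome 10 took 5.30% and 5.33% of reads in WT and 5.31% and 5.32% in Oshmgb1, and chromosome 12 took 10.8% and 10.4% against 10.5% and 10.5%. The shares of the 2 genotypes did not overlap on chromosomes 6 (7.48% and 7.42% in WT, 7.32% and 7.39% in Oshmgb1), 4 (7.84% and 7.95%, 8.04% and 8.03%) and 11 (5.11% and 5.24%, 5.25% and 5.25%), and overlapped on the other 9. By class, promoter peaks took 39.9% and 38.7% of reads in WT and 38.5% and 39.3% in Oshmgb1, and only the 5′ UTR shares did not overlap (7.49% and 7.25%, 7.19% and 7.24%).

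**Figure D3:**
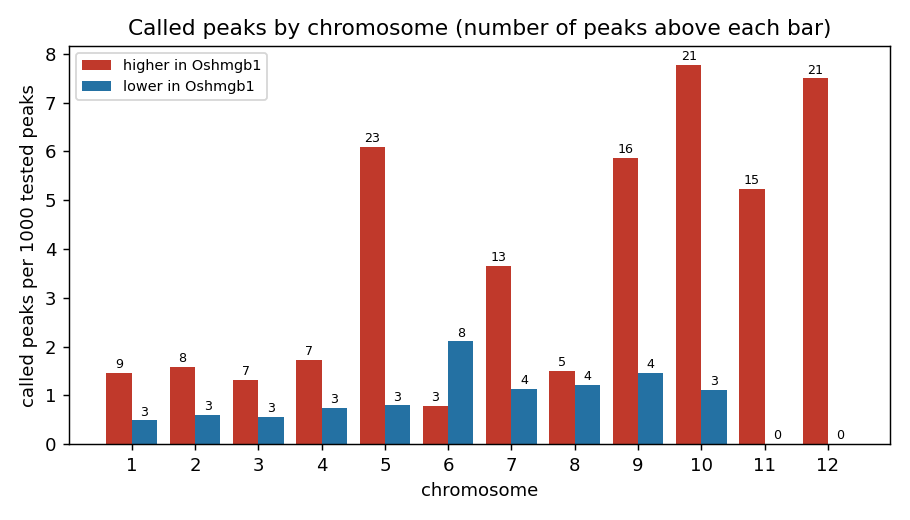
Called peaks per 1000 tested peaks on each of the 12 chromosomes, with peaks higher in Oshmgb1 in red, lower in blue and the number of peaks above each bar. Chromosomes 10 and 12 have the tallest red bars, 7.77 and 7.50 per 1000, and chromosome 6 the tallest blue bar, 2.11 per 1000.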

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

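The intensity-dependent offset, the restriction to peaks of at least median abundance, the thinning to one depth and the matching without letter case were chosen after the data were seen; the other alternatives were planned. The count of 186 called peaks became 45 with DESeq2, 47 in the authors' deposited table, 77 at an adjusted p under 0.01 and 101 with an absolute log2 fold change of at least 1. It became 59 among peaks of at least median abundance and 115 after thinning. The lower counts at a stricter threshold or with fewer peaks or reads follow from their construction, and for DESeq2 and the deposited table the cause was not tested. Leaving out 1 library gave 75 (Oshmgb1 replicate 2) to 530 (WT replicate 2), with 103 without Oshmgb1 replicate 1 and 198 without WT replicate 1, and the cause was not tested. DESeq2 size factors gave 191, library totals alone 203, the totals behind the RPKM 221 and the offset 142. Filters and unplaced sequences changed no call. No called peak turned its direction under any of these alternatives. The higher share was 79.6%, and 60.2% with the totals behind the RPKM, 67.6% with the offset, 93.3% with DESeq2 and 90.9% at an adjusted p under 0.01.

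Deviations of replicate 1 from replicate 2 correlated at -0.04 between genotypes, over 2 pairs, so no effect shared by the replicate numbers was seen. With 2 pairs, and labels that do not say, this cannot show that libraries of the same number shared no day or batch. The replicate block gave 179 called peaks, 171 of them shared with the fit without it, 0 lists past camera, 2 tests of annotation classes past the threshold (downstream and 3′ UTR) and 1 list, the MYB factors, up in the one-directional fry test (adjusted p 0.0159, against 0.725 without the block, cause not tested). For gene lists, camera passed 0 lists in every alternative except without WT replicate 2, where 1 list, the ethylene response factors, passed with an adjusted p of 0.0465 (range over left-out libraries 0 to 1, cause not tested). The receptor kinase odds ratio of 15.3 turned to 0.864 without WT replicate 2, where 1 of 263 peaks was lower, and ranged from 0 (no lower peak called, without either Oshmgb1 replicate) to 8.12 over the left-out libraries, and the cause was not tested. The odds ratio of lower peaks on chromosome 6, 2.98, became 0.929 without Oshmgb1 replicate 2 and ranged to 1.86 over the left-out libraries, and the cause was not tested. The count of tests past the threshold, each of 1 annotation class in 1 direction, 1 by default, was 2 with gene body classes pooled (downstream more often and gene body less often higher), 0 with an absolute log2 fold change of at least 1, 3 with library totals alone (downstream and both UTR classes) and 0 to 6 over the left-out libraries, lowest without Oshmgb1 replicate 1 and highest without WT replicate 2 (downstream and exons more often higher, promoters and both UTR classes less often, and 3′ UTRs less often lower), and the cause was not tested. The pseudocount alternative was not run because counts were tested. At this depth, spread and number of libraries, 20% of simulated 1.5-fold changes were recovered, and the parts of the 3 were not separated.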

Other observations

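The tests of KEGG pathways, GO terms, transposon-like genes and neighbouring peaks, those of the first pattern, that of whole chromosomes and the chi-square tests, which replaced 2 earlier tests on 5 chosen chromosomes, were chosen only after the data were seen. The genes with the lowest camera p-values were those of ubiquinone and terpenoid-quinone synthesis (30 promoter peaks, median log2 fold change -0.18) and of the terpenoid backbone (31 peaks, median -0.16), the routes to plastoquinone, tocopherol and isoprenoid precursors. Neither passed, with an adjusted p of 0.0553 each over 106 pathways, 0.939 with an estimated correlation, and 0.0953 and 0.173 with the intensity-dependent offset. Of 180 tests of GO terms among called peaks 0 passed, the lowest adjusted p being 0.425. Peaks at transposon-like genes were called in both directions, 11 of 776 higher (odds ratio 4.74, adjusted p 9.07e-05) and 4 lower (odds ratio 6.90, adjusted p 0.00560, two-sided Fisher's exact test). They included RE2 and TY3B-I entries. This class was set by symbols as well as descriptions. The planned list of transposon-related genes, set by descriptions alone, had 0 of 123 peaks of any class higher and 1 lower, and thus showed no such gain. Fisher's test counts peaks as independent, though 2 of the higher TY3B-I peaks lie side by side at LOC_Os12g08040.

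Called higher peaks also lay side by side, with 23 of them in 10 groups spaced by less than 10 kb. All 10 groups lie on chromosomes 9, 10, 11 and 12. Whether this is more than the spacing of the tested peaks would give was not tested. The longest group, 4 peaks on chromosome 11 from 27464876 to 27473929, lies at WAV3 (LOC_Os11g45390, a von Willebrand factor type A domain protein), with log2 fold changes of 0.86 to 1.53. A group of 3 lies on chromosome 10 from 12297648 to 12301153 (0.61 to 1.69), and pairs lie at LOC_Os10g22630, at the NADH kinase gene LOC_Os09g17680 and at LOC_Os09g20190.

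The first pattern is the excess of higher peaks, 148 against 38, with 59 of the 148 in the lowest decile by abundance, where the median log2 fold change was 0.11 against -0.05 in the highest decile. A trend with intensity is argued against as the whole cause. With an offset that removes it, 67.6% of 142 calls were still higher (95% interval 59.2 to 75.2). The intervals in this paragraph count called peaks as independent and do not measure the spread between libraries. A peak set drawn mainly from the deeper mutant libraries stays open. Among peaks of at least median abundance 86.4% of 59 calls were higher, but that abundance is taken over all 4 libraries. Peaks weak in WT can thus enter through their mutant reads. Scaling stays open too, since with the totals behind the RPKM the higher share was 60.2% (95% interval 53.4 to 66.7). There 133 of the 148 higher calls were kept, and lower calls numbered 88 against 38. The genotype itself stays open as a biological explanation that was not tested apart from scaling. With 3 splits of the 4 libraries no share under 0.05 can be reached: only 1 split, the real one, called as many as 186, and the highest other called 0. Each other split puts 1 library of each genotype in each arm. Any difference between genotypes then adds to the spread within arms and lowers the calls, so this contrast is partly built in.

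The second pattern is the concentration of higher peaks on chromosomes 5, 9, 10, 11 and 12, chosen after their counts were seen, which hold 96 of 148 higher peaks (64.9%) but 32.3% of tested peaks and 10 of 38 lower peaks. Since that choice came from the counts, weak peaks were tested on all 12 chromosomes and are argued against as the whole cause. The chi-square was 74.9 against at most 28.7 in 1000 draws matched on abundance (p 0.001, the smallest they can give). It ranged from 41.7 to 62.4 with a library left out, lowest without WT replicate 2. Without Oshmgb1 replicate 1 it was 42.6, and the highest draw reached 61.4. A shift of whole chromosomes is argued against too (0.018 between their medians), and so are long copy gains at most of the higher peaks. Uncalled peaks within 20 kb of the higher peaks had a median log2 fold change of 0.049, or 0.06 with called neighbours. This lies above the -0.02 to 0.02 of abundance-matched peaks. A median over all places cannot exclude gains at some of them, such as the group at WAV3. Runs of higher peaks spaced by less than 50 kb are argued against as the whole cause. At 1 peak per 50 kb the chi-square was 52.0 against at most 33.5 in the matched draws (p 0.001). Of the peaks kept, 60.6% lay on these chromosomes. Among all higher peaks that share was 46.3% without WT replicate 2 and 58.4% to 75.8% without the others. Higher peaks spread more widely along a long linked segment would remain after this step, so such segments stay open. Copy gains at some places, small insertions, sequence differences between the plants and an effect of the genotype stay open, since no reads were used here.

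The third pattern is that 67 of 148 higher peaks (45.3%) lay at genes without a name or description, against 26.8% of tested peaks (odds ratio 2.27). Lower abundance at such genes is argued against as the whole cause, with an odds ratio of 1.94 (95% interval 1.40 to 2.68) after stratifying by abundance decile. Their place on particular chromosomes is argued against likewise, with 2.13 (1.53 to 2.95) after stratifying by chromosome. Both intervals count peaks as independent, though some lie at the same gene, and do not measure the spread between libraries. The odds ratio was 1.76 to 3.55 with a library left out, the lowest without WT replicate 2 and the highest without Oshmgb1 replicate 2. A candidate explanation left open is reads shared between repeated copies, which counts alone do not show, beside an effect of the genotype.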
